A study of Homo sapiens with 3 samples.

How the data were processed

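Total RNA of H82R small cell lung cancer cells was extracted with TRIzol and made into Illumina libraries, per the labels' protocols. The values are raw read counts per gene symbol, deposited by the authors as 1 table with 1 column for each of the 3 libraries. STAR 2.6.1b and the genome build hg38 are named in the submitters' processing notes, with no role given. The counting program, the annotation and the strand setting are not given in the sources used here, and neither is any filter. Each column was matched to its library by its title. The counts are whole numbers that sum to different totals, and the deposited values were not normalized.

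The table held 27587 names. Of these, 13 had been turned into dates, as a spreadsheet does with some gene symbols, and no longer name 1 gene; they held 0.0665%, 0.0707% and 0.0736% of the counts in replicates 1, 2 and 3 and were left out of totals and tests, which leaves 27574 genes. Totals were 25013265, 42610181 and 23868201 counts. Effective library sizes were these totals times TMM factors from edgeR 4.0.16 (0.993, 1.00 and 1.00), and CPM were computed from them. A gene with at least 10 counts in every library was called detected. For log2 CPM a prior count of 2 was added. Floors and intervals cover counting error only: a count of 0 was taken to allow up to 3 counts, and ratios within a library have exact (Clopper-Pearson) 95% binomial intervals. Reads without molecular identifiers are not independent molecules.

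The labels form 1 group, so no test between groups could be made, and edgeR's quasi-likelihood and DESeq2's tests, which need a contrast, were not run. Whether a gene lies above or below the typical detected gene was tested with limma-trend (limma 3.58.1, R 4.3.3) as a two-sided one-sample moderated test of log2 CPM minus the median over detected genes of the same library, with Benjamini-Hochberg adjustment over all detected genes and a threshold of 0.05. It was also adjusted over each list alone. Whether a gene list lies high or low was tested with a two-sided permutation test across genes: the median of its detected members against 10000 random lists of the same size from all detected genes, adjusted over the 31 lists with at least 3 detected members. Genes are not independent replicates. Spread beyond counting error was tested with a chi-square test of homogeneity per gene against effective library sizes, adjusted over detected genes. Ratios of 21 fixed gene pairs were tested with a two-sided exact sign-flip test.

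The 35 gene lists, the 21 pairs, the tests and the alternatives were fixed before the data were examined, except where the text says otherwise. They cover subtype factors, neuroendocrine, neuronal bHLH, tuft-cell, mesenchymal, epithelial, NOTCH, MYC, cell cycle, p53, proliferation, topoisomerase, transporter, redox, DNA repair (4 lists), checkpoint, apoptosis, chromatin, surface, antigen presentation, interferon, hypoxia, stemness, stress and reference genes, and markers of 6 other cell types. Genes named are the 10 most abundant, every subtype factor, MYC family and topoisomerase list member, every pair member, the 3 highest and the lowest detected member of each other list, and the 10 genes with the largest SD of log2 CPM among detected genes past the homogeneity test with a mean of at least 50 counts. Some genes, 1 list and some pairs that this rule names entered every test and are not reported here.

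Gene type, position, exon length and GC content came from GENCODE release 29 on GRCh38, the assembly that hg38 names. Of the 27574 names, 19590 matched it directly and 478 through an older symbol in a RefSeq table, and 7506 did not match; exon length was known for 92.5% of detected genes and for all 450 list genes. In the table CCN1, CCN2, CGAS and STING1 carry the names CYR61, CTGF, MB21D1 and TMEM173. For the share of coding bases that a gene has in common with another gene on the same strand, the same annotation was used, which need not be the one the authors counted with.

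The alternatives were leaving out each library, filters of at least 1 CPM in every library and of at least 1 count in any library, DESeq2 1.42.0 size factors, plain totals, a prior count of 0.5, limma-voom, the upper quartile as reference point, random lists matched on length, CPM per kb of exon, protein-coding genes only, and a threshold of 0.01 for the homogeneity test. A further alternative, chosen after seeing the data, left out genes with at least 50% of their coding bases shared with another gene.

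The tests were tested on simulated data for the 14612 detected genes. At no distance from the median gene limma's test called 4% of 1000 simulated genes, and at a log2 distance of 0.5 or -0.5 it called 96%. The homogeneity test called 86% of 100 genes changed 1.5-fold in 1 library, 95% of 100 genes changed 2-fold, and 0.0902% of genes with counting noise only. The list test gave an unadjusted p under 0.05 for 4% of 100 random lists. It called 96% of 50 lists drawn from the upper part of the genes high, at an adjusted p under 0.05. Both kinds of list were random draws from the gene values that the test itself uses. These 2 rates therefore check the computation and say nothing of lists of related genes. Figures were drawn with matplotlib 3.10.9.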

Results

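RNA sequencing read counts were available for 3 libraries of H82R cells, named here replicate 1, 2 and 3. H82 is an established human small cell lung cancer cell line, and the labels give etoposide plus cisplatin as the treatment of all 3 libraries. Etoposide traps type II topoisomerases on DNA and cisplatin forms DNA adducts and crosslinks. The labels form 1 group and name no untreated or parental sample, so the data give the level of each gene in these cells and its spread between libraries, not the effect of the treatment. Replicates 1, 2 and 3 held 25013265, 42610181 and 23868201 counts over 27574 genes. Of these genes, 14612 had at least 10 counts in every library and are called detected, and 5548 had no count in any library. The median detected gene stood at 25.2 CPM, the count scaled to a common library size. A count of 0 allowed up to 0.121, 0.0702 and 0.125 CPM in replicates 1, 2 and 3 (3 counts). Nothing in the labels says that the libraries came from separate cultures, so the p-values of limma's, the homogeneity and the sign-flip test measure only the spread between these samples, which may be technical, while those of the gene lists compare genes with other genes.

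H82R cells held high levels of NEUROD1, a neuronal transcription factor that defines 1 of the small cell lung cancer subtypes, at 371 CPM ± 39.7 (SD, n = 3). YAP1, a Hippo pathway coactivator, stood at 24.2 ± 3.17 CPM. POU2F3, the tuft-cell factor, had 2, 2 and 1 counts in replicates 1, 2 and 3. NEUROD1 counts exceeded those of YAP1 by 14.8, 14.3 and 17.0 times in the 3 libraries. Against POU2F3 the ratio was 5109 in replicate 1 (95% exact binomial interval 1414 to 42192), 7095 in replicate 2 (1964 to 58591) and 8875 in replicate 3 (1592 to 350583). In limma's one-sample test against the median detected gene, NEUROD1 lay above it by 3.88 ± 0.08 (SE) on the log2 scale (adjusted p = 2.2e-09), while YAP1 was not distinguished from it (adjusted p = 0.608). On GRCh38, NEUROD1 lies on chromosome 2 from 181673088 to 181680876 and YAP1 on chromosome 11 from 102110461 to 102233423.

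Of 18 neuroendocrine markers, 16 were detected, 12 of them above the median gene and 4 below, and the undetected members were GRP and CALCA. UCHL1 (326 ± 7.81 CPM), ENO2 (233 ± 36.8 CPM) and SYP, which encodes synaptophysin (207 ± 6.20 CPM), were the 3 highest, and SCG2 (2.02 ± 0.238 CPM) was the lowest detected. The list as a whole was not distinguished from random lists of detected genes (permutation test, adjusted p = 0.136), but it was called high without replicate 3 (adjusted p = 0.0348) and on CPM per kb of exon (0.0393), with 0.0319 to 0.252 over its 12 alternatives. In the neuronal bHLH programme, 6 of 9 genes were detected and 4 lay above the median gene, among them the NOTCH-pathway repressor HES6 (127 ± 15.5 CPM) and EYA2 (81.2 ± 15.3 CPM). The somatostatin receptor SSTR2 stood at 22.7 ± 1.65 CPM and was not distinguished from the median gene. All 3 detected tuft-cell markers, of 8 fixed, lay below the median gene: CHAT (18.8 ± 4.54 CPM), AVIL (3.74 ± 0.295 CPM) and SOX9 (0.859 ± 0.418 CPM). Neither the bHLH list (adjusted p = 0.416), the tuft list (0.416) nor the 3 detected subtype factors of 4 (0.999) differed from random lists in the permutation test. Adjusted over the list alone, the counts of genes above and below were the same as over all detected genes for all 35 lists except 1, which is named with its count.

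MYC was the leading member of its family, at 792 ± 149 CPM. MYCL reached 55.6 ± 8.29 CPM, MYCN 3.19 ± 0.446 CPM, and MAX, the shared dimerisation partner of MYC proteins, 53.3 ± 10.2 CPM. MYC counts were 253, 214 and 276 times those of MYCN in replicates 1, 2 and 3, and 17.5, 9.90 and 16.4 times those of MYCL. Of the 4 genes, 3 lay above the median gene and MYCN below it; the list was not distinguished from random lists (permutation test, adjusted p = 0.416). MYC lies on chromosome 8 from 127735434 to 127741434. MYCN has an annotated antisense neighbour, and its reads cannot be told from those of that neighbour because the strand setting of the counting is not given.

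All 24 proliferation genes were detected and all lay above the median gene, and the list stood high among detected genes, with a median log2 CPM of 7.09 against a central 95% of 3.14 to 5.68 in 10000 random lists (permutation test, p = 2.0e-04, the smallest they can give, adjusted p = 0.00207). TOP2A (1031 ± 176 CPM), the proliferation antigen gene MKI67 (568 ± 74.7 CPM) and the replication helicase gene MCM4 (480 ± 30.4 CPM) led it, and its lowest member, CCNB2, stood at 66.9 ± 2.16 CPM. Of 17 RB and G1 cell cycle genes, 11 lay above and 3 below the median gene and CCND1 was not detected. E2F3 (202 ± 20.8 CPM), CDK6 (160 ± 22.5 CPM) and E2F1 (143 ± 12.1 CPM) were highest, and RB1, the retinoblastoma tumour suppressor, was the lowest detected member at 6.62 ± 0.996 CPM. The CDK inhibitor gene CDKN2A, which also has an antisense neighbour, stood at 138 ± 14.1 CPM, whereas the p53 target CDKN1A had 3, 11 and 2 counts; the CDKN2A to CDKN1A ratio was 1253 in replicate 1 (95% exact binomial interval 429 to 6080), 537 in replicate 2 (300.1 to 1077) and 1476 in replicate 3 (408 to 12198). Among p53 and its targets 8 of 21 genes lay above the median gene, 6 below, 4 were not distinguished and 3 were not detected. MDM2 (110 ± 12.1 CPM), SESN2 (105 ± 38.4 CPM) and GADD45A (69.1 ± 12.1 CPM) were the highest and FAS (0.771 ± 0.179 CPM) the lowest detected. Neither the G1 list (adjusted p = 0.416) nor the p53 list (0.878) differed from random lists in the permutation test.

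**Figure D1:**
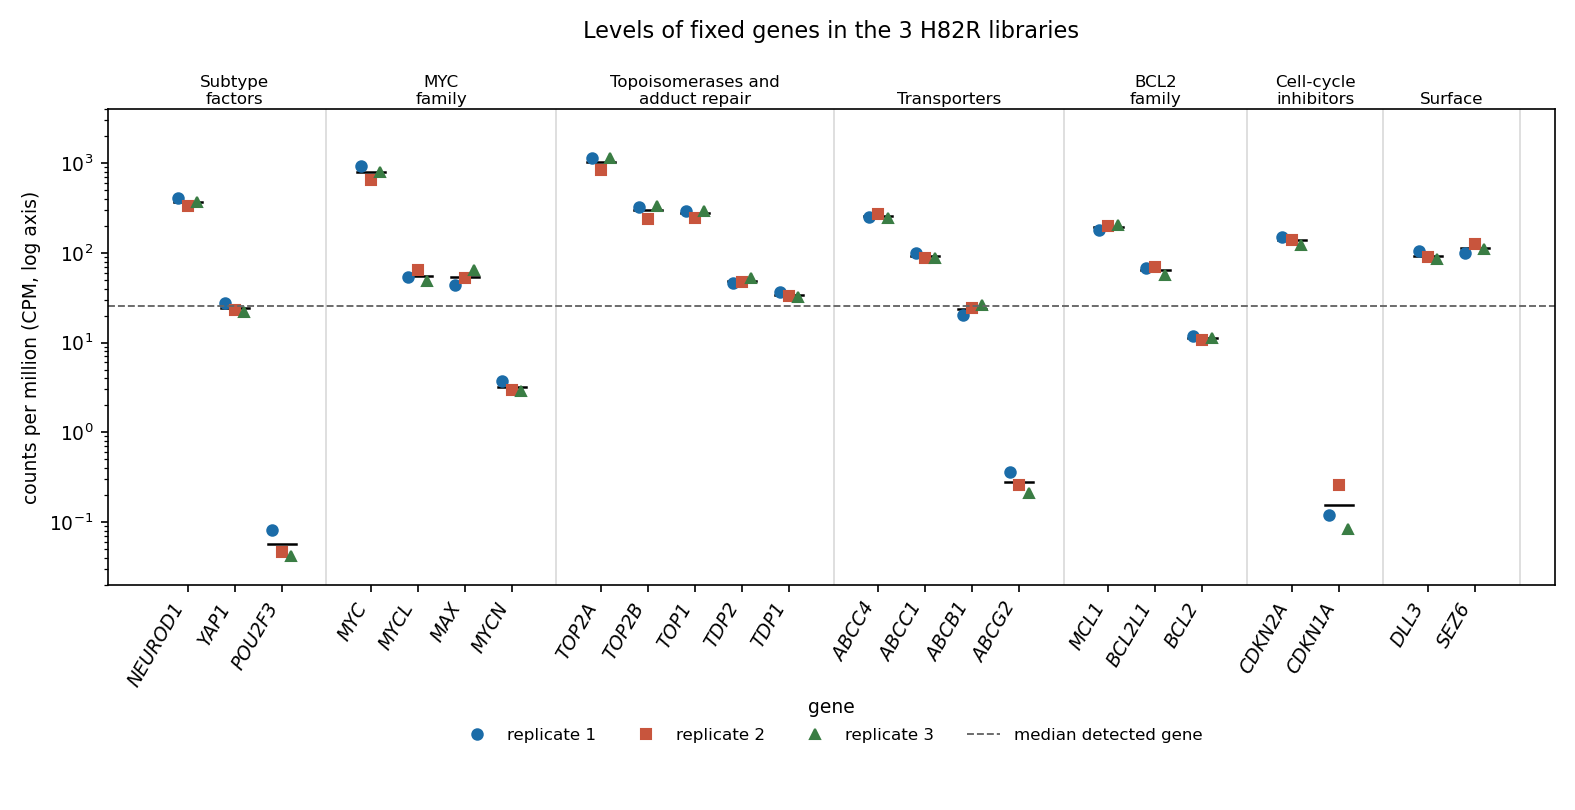
CPM (log axis) of fixed genes in the 3 H82R libraries; each symbol is 1 library, the short line is the mean of 3, and the dashed line marks the median detected gene at 25.2 CPM. NEUROD1, MYC and TOP2A lie above that line in every library, and POU2F3, ABCG2 and CDKN1A lie far below it.

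The genes for the etoposide targets TOP2A and TOP2B, for TOP1 and for the repair of topoisomerase adducts were all expressed above the median gene. TOP2A stood at 1031 ± 176 CPM, TOP2B at 299 ± 50.4 CPM and TOP1 at 278 ± 29.3 CPM (SD, n = 3). The tyrosyl-DNA phosphodiesterases TDP1 and TDP2, which remove trapped topoisomerases, were lower, at 34 ± 2.30 and 48.9 ± 3.38 CPM. TOP2A exceeded TOP2B by 3.49, 3.44 and 3.42 times in replicates 1, 2 and 3, the narrowest spread on the log2 scale of the 21 fixed ratios, and TDP1 was 0.788, 0.703 and 0.609 times TDP2. All 5 genes lay above the median gene, and the list stood high among detected genes (permutation test, adjusted p = 0.00744). TOP2A lies on chromosome 17 from 40388516 to 40417950.

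Among 16 drug uptake and efflux transporters, the multidrug resistance protein genes ABCC4 (255 ± 14.5 CPM), ABCC1 (91.5 ± 7.23 CPM) and ABCC5 (85.9 ± 15 CPM) were highest. ABCB1, which encodes P-glycoprotein, stood at 23.7 ± 3.09 CPM and was not distinguished from the median gene, and ABCG2 had 9, 11 and 5 counts. ABCC1 counts were 4.91, 3.61 and 3.29 times those of ABCB1 and 275, 341 and 416 times those of ABCG2. The copper importer gene SLC31A1, whose product also carries cisplatin, reached 59.4 ± 1.79 CPM, against 7, 12 and 2 counts of SLC31A2, with ratios of 211 in replicate 1 (95% exact binomial interval 102 to 526), 205 in replicate 2 (117 to 397) and 732 in replicate 3 (202 to 6050). The copper exporter gene ATP7A (26.9 ± 1.04 CPM) stood at 0.75, 0.759 and 0.829 times ATP7B (34.6 ± 2.36 CPM). ABCC6 was the lowest detected transporter at 1.47 ± 0.230 CPM, a level that depends on how reads shared with its pseudogenes were counted. Of the list, 7 genes lay above and 3 below the median gene, 2 were not distinguished and 4 were not detected (permutation test of the list, adjusted p = 0.416).

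Glutathione, metallothionein and redox genes split: 12 of 20 lay above the median gene, 5 below and 3 metallothionein genes were not detected. GSTP1, a glutathione transferase, reached 361 ± 37.3 CPM, the thioredoxin reductase gene TXNRD1 209 ± 9.65 CPM and the glutathione reductase gene GSR 176 ± 5.53 CPM, while MT1F, 1 of several near-identical metallothionein copies, stood at 0.594 ± 0.0610 CPM. The list was called high (permutation test, adjusted p = 0.0351). On CPM per kb of exon the call was lost (adjusted p = 0.0523, from 0.00175 to 0.0523 over its 12 alternatives).

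DNA repair genes were widely expressed. All 23 homologous recombination and Fanconi genes, all 17 nucleotide excision and translesion repair genes and all 7 mismatch repair genes were detected, as were 10 of 11 end joining genes. The end joining kinase gene PRKDC reached 2226 ± 76.9 CPM, with XRCC5 at 707 ± 20.9 CPM and XRCC6 at 465 ± 21 CPM. PRKDC lies on chromosome 8 from 47773108 to 47960183, next to MCM4. In nucleotide excision repair, DDB1 (418 ± 8.22 CPM) and RAD23B (291 ± 23.7 CPM) were highest. BRCA1 (152 ± 25.2 CPM), FANCI (136 ± 10.8 CPM) and FANCA (72.5 ± 11.1 CPM) led the recombination list, and MSH6 (257 ± 18.7 CPM) the mismatch list. The lowest detected members of the end joining, excision and mismatch lists were DCLRE1C (16.0 ± 2.59 CPM), ERCC5 (2.72 ± 0.604 CPM) and MLH3 (1.35 ± 0.334 CPM). In the reference annotation 97.8% of the coding bases of ERCC5 also belong to another gene on the same strand, so its count is uncertain.

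Above and below the median gene stood 17 and 2 of the recombination genes (16 and 2 adjusted over the list alone), 11 and 4 of the excision genes, 8 and 1 of the end joining genes and 5 and 2 of the mismatch genes. None of these 4 lists differed from random lists in the permutation test (adjusted p = 0.416, 0.527, 0.416 and 0.552), but the recombination list was called high when any gene with a count was kept (0.0363, from 0.0363 to 0.801 over its 12 alternatives). Among 12 damage checkpoint genes, 10 lay above the median gene and none below. PARP1 (712 ± 33.1 CPM), TIMELESS (182 ± 16.0 CPM) and CLSPN (177 ± 25.3 CPM) were highest, ATRIP (21.7 ± 0.473 CPM) was not distinguished from the median gene, and SLFN11, a replication-stress factor named here after its values were seen, was the 1 undetected member, with 1, 0 and 0 counts. PARP1 exceeded PARP2 (46.4 ± 3.66 CPM) by 14.5, 15.3 and 16.3 times. The kinase gene CHEK1 (80.3 ± 2.86 CPM) was 1.45, 1.51 and 1.5 times CHEK2 (54.0 ± 2.31 CPM), and per kb of exon the mean ratio was 1.02. The checkpoint list missed the threshold (permutation test, adjusted p = 0.0620) and passed it without replicate 3 (adjusted p = 0.0328, from 0.0117 to 0.207 over its 12 alternatives).

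Of 22 apoptosis regulators, 8 lay above the median gene and 10 below. The antiapoptotic genes MCL1 (193 ± 12.1 CPM) and BCL2L2 (182 ± 27 CPM) and the caspase inhibitor gene XIAP (97.1 ± 8.07 CPM) were highest and BIRC3 (1.19 ± 0.0534 CPM) lowest; in the reference annotation 61.5% of the coding bases of BCL2L2 are shared with another gene. BCL2L1 stood at 64.9 ± 7.24 CPM and BCL2 at 11.2 ± 0.530 CPM. MCL1 counts were 15.3, 18.3 and 18.2 times those of BCL2 and 2.63, 2.82 and 3.59 times those of BCL2L1, and BCL2 was 0.173, 0.154 and 0.198 times BCL2L1. The list was not distinguished from random lists (permutation test, adjusted p = 0.726).

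Chromatin regulators were abundant: 16 of 17 lay above the median gene, and EED (27.4 ± 2.01 CPM) was not distinguished from it. The DNA methyltransferase gene DNMT1 (761 ± 38.7 CPM), the histone demethylase gene KDM1A (467 ± 34.1 CPM) and the histone methyltransferase gene KMT2D (439 ± 18.8 CPM) were highest. EZH2, the catalytic subunit of Polycomb repressive complex 2, stood at 167 ± 29.5 CPM, which was 3.41, 2.86 and 4.60 times its paralog EZH1 (46.6 ± 3.03 CPM). The list was called high (permutation test, adjusted p = 0.00207). On CPM per kb of exon its call was lost (adjusted p = 0.107, from 0.00175 to 0.107 over its 12 alternatives).

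Of 14 epithelial genes, 8 were detected, 7 of them below the median gene: KRT8, which has many processed pseudogenes, stood at 29.2 ± 4.65 CPM and was not distinguished from it, ESRP1 at 2.64 ± 1.10 CPM, CLDN4 at 2.33 ± 0.613 CPM and KRT7 at 0.636 ± 0.182 CPM. Mesenchymal and non-neuroendocrine genes lay above the median gene in 2 and below it in 10 of 19 cases, with the neural cadherin gene CDH2 (61.8 ± 2.94 CPM) and the transcription factor genes ZEB1 (55.2 ± 20.3 CPM) and ZEB2 (25.9 ± 1.88 CPM) highest and CD44 (1.29 ± 0.179 CPM) lowest. VIM, which encodes vimentin, stood at 10.7 ± 2.95 CPM and CDH1, which encodes E-cadherin, had 4, 24 and 7 counts. The VIM to CDH1 ratio was 75.8 in replicate 1 (95% exact binomial interval 29.3 to 279.8), 22.5 in replicate 2 (14.9 to 35.4) and 25 in replicate 3 (11.9 to 63.1). In the NOTCH pathway 4 of 17 genes lay above the median gene and 10 below: NOTCH2 (154 ± 29.7 CPM), whose reads can be shared with its partial copies, the inhibitory ligand gene DLL3 (92.8 ± 9.68 CPM) and JAG2 (79.7 ± 5.18 CPM) were highest and NOTCH4 (0.581 ± 0.0847 CPM) lowest. Neither the epithelial (adjusted p = 0.0654), the mesenchymal (0.416) nor the NOTCH list (0.0654) passed the permutation test against all detected genes. Against detected protein-coding genes alone, the epithelial and the NOTCH list were both called low (adjusted p = 0.0204 each), and the epithelial list was also called low without replicate 2 (0.0496). Over 12 alternatives the adjusted p ranged from 0.00672 to 0.458 for the epithelial and from 0.0204 to 0.697 for the NOTCH list.

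Among 17 surface antigens and receptors, 7 lay above and 5 below the median gene. The insulin-like growth factor receptor gene IGF1R (269 ± 9.52 CPM), SEZ6 (112 ± 12.3 CPM) and DLL3 (92.8 ± 9.68 CPM) were highest and FGFR1 (5.58 ± 0.726 CPM) lowest, while 4 were not detected, among them CEACAM5, EGFR and KIT. The order of DLL3 and SEZ6 differed between libraries, with ratios of 1.03, 0.711 and 0.781 (exact sign-flip test, p = 0.50). Antigen presentation genes lay above the median gene in 4 and below it in 5 of 17 cases, and 7 were not detected, among them HLA-B, TAP2, PSMB8, PSMB9 and NLRC5. The chaperone genes CANX (929 ± 104 CPM) and CALR (421 ± 41.9 CPM) were highest, and TAP1 was the lowest detected at 1.02 ± 0.0887 CPM. B2M, which encodes beta-2-microglobulin, stood at 65.3 ± 1.12 CPM. Of 19 interferon response genes 13 were not detected, 2 lay above and 4 below the median gene: STAT2 stood at 46.3 ± 2.66 CPM, IFI6 at 6.48 ± 0.468 CPM and IFIT1 at 0.665 ± 0.135 CPM. The surface (adjusted p = 0.416), antigen presentation (0.697) and interferon (0.210) lists were not distinguished from random lists in the permutation test, though the interferon list was called low without replicate 3 (adjusted p = 0.0165, from 0.0165 to 0.676 over its 12 alternatives).

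Hypoxia and glycolysis genes lay above the median gene in 10 and below it in 2 of 15 cases, with the glycolytic genes ENO1 (2103 ± 202 CPM), LDHA (615 ± 117 CPM) and PGK1 (460 ± 27.4 CPM) highest. ALDOA stood at 0.945 ± 0.204 CPM, but 93.8% of its coding bases are shared with another annotated gene. Of 11 stemness genes 6 were detected, 3 above and 2 below: LIN28A, an RNA-binding repressor of let-7, reached 358 ± 29.2 CPM, PROM1 115 ± 8.03 CPM, BMI1, all of whose coding bases are shared with another gene, 41.0 ± 5.49 CPM, and KLF4 0.626 ± 0.127 CPM. Of 15 immediate early and stress genes 7 lay above and 4 below: ATF4 (568 ± 87.3 CPM), HSPA5 (403 ± 59.1 CPM) and HSPH1 (199.6 ± 54.7 CPM) were highest and FOSB (0.672 ± 0.0829 CPM) lowest. These 3 lists were not distinguished from random lists (permutation test, adjusted p = 0.0781, 0.766 and 0.416), but the hypoxia and glycolysis list was called high when any gene with a count was kept (0.0149, from 0.0149 to 0.546 over its 12 alternatives). The 10 reference genes all lay above the median gene and their list was called high (permutation test, adjusted p = 0.00207), from RPLP0 (2989 ± 251 CPM), ACTB (2396 ± 132 CPM) and GAPDH (2050 ± 174 CPM) to TBP (30.8 ± 1.88 CPM). The 10 most abundant genes were MT-CO1 (23012 ± 1896 CPM), EEF1A1 (13881 ± 1364 CPM), MT-ND4, MT-ND2, MT-CO3, MT-CO2, EEF2, MT-ND1, MT-ATP6 and MT-CYB (3989 ± 136 CPM), 8 of them mitochondrial, whose reads can be shared with nuclear copies.

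Markers of other cell types were mostly undetected. One label calls the samples tumour, while the growth protocol describes cell culture, so lists for the cells of a tissue were examined. These lists hold human genes, so cells of a host of another species need not show in them. Undetected markers therefore cannot tell a culture of this human line from its graft in such a host. Of 11 fibroblast markers 3 were detected, all below the median gene: THY1 (7.56 ± 0.892 CPM), PDGFRB (3.52 ± 0.863 CPM) and COL1A1 (0.685 ± 0.298 CPM). All 4 detected endothelial markers of 8 lay below it, namely EMCN (1.03 ± 0.261 CPM), PECAM1 (0.876 ± 0.411 CPM), ERG (0.677 ± 0.181 CPM) and VWF (0.406 ± 0.0102 CPM), and the list was called low (permutation test, adjusted p = 0.00744), a call lost when any gene with a count was kept (adjusted p = 0.279, from 0.00207 to 0.279 over its 11 alternatives). The fibroblast list was not distinguished (adjusted p = 0.416), but was called low when any gene with a count was kept (0.0363, from 0.0363 to 0.438 over its 11 alternatives). Of 9 myeloid markers only CD68 was detected, at 22.6 ± 3.71 CPM, which was not distinguished from the median gene, and 97.6% of its coding bases are shared with another gene; CSF1R had 28, 54 and 8 counts and CD14 10, 16 and 4. Of 9 lymphoid markers only CD3E was detected, below the median gene at 7.62 ± 2.23 CPM; CD8A had 4, 21 and 3 counts and PTPRC, the pan-leukocyte gene CD45, 6, 10 and 7. None of 5 erythroid markers was detected, with 13, 26 and 4 counts of ALAS2 and 0, 1 and 2 of HBB. Of 8 lung epithelial markers FOXJ1 (12.1 ± 2.99 CPM) and AGER (1.54 ± 0.194 CPM) were detected, both below the median gene, and MUC5B had 3, 7 and 4 counts. These last 4 lists had fewer than 3 detected members and were not tested for position.

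**Figure D2:**
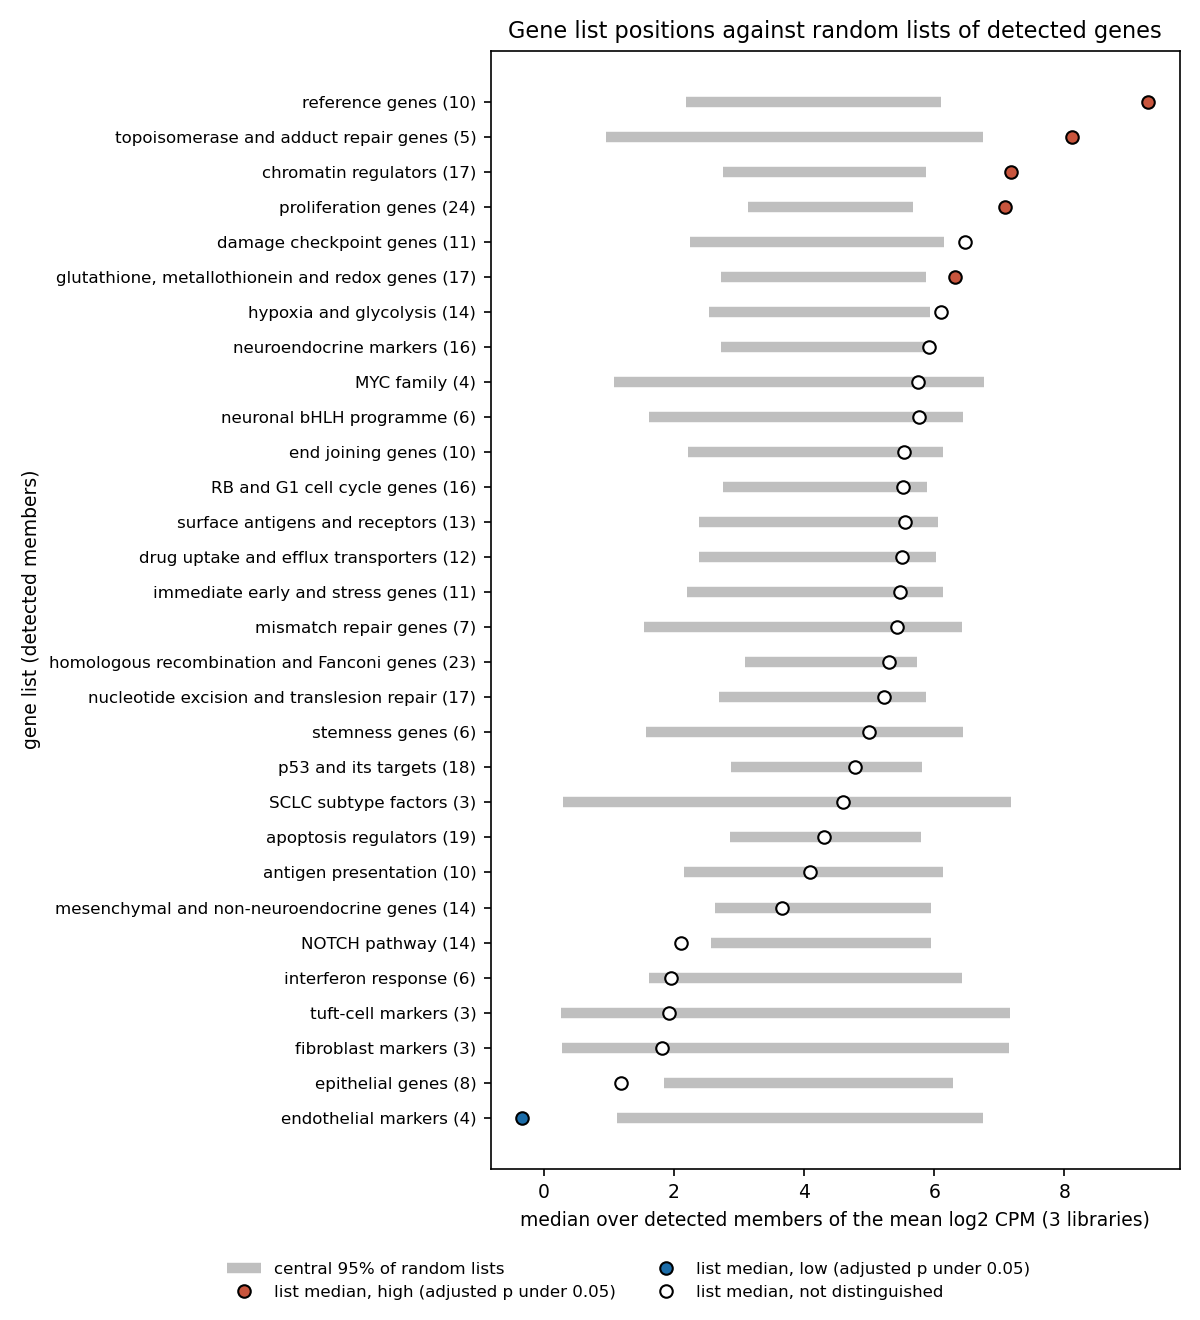
Median log2 CPM of the detected members of the tested gene lists (circles, mean of 3 libraries) against the central 95% of 10000 random lists of detected genes (grey bars); filled circles passed the adjusted permutation test. The 5 lists called high include proliferation genes and chromatin regulators, and the endothelial list is the 1 called low.

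Over all detected genes, 6705 lay above and 6736 below the median detected gene of the same library in limma's test (adjusted p under 0.05). Only 1171 were not distinguished from it. A near-even split follows from centring each library on its median, and most detected genes were called. The counts above and below within a list are to be read beside these counts. Of 31 tested lists, 5 were called high, 1 low and 25 were not distinguished. Of 21 fixed ratios, 20 had the same order in all 3 libraries, DLL3 to SEZ6 being the exception, and with 3 libraries the exact sign-flip test cannot go below p = 0.25. CPM are not divided by gene length, so a ratio between genes also carries their lengths. The same holds for the place of a gene above or below the median gene and for its rank within a list. Those calls of single genes were not repeated per kb of exon. Per kb of exon, the geometric mean ratio moved by over 1.5 times for NEUROD1 to YAP1 (15.3 to 29.2), NEUROD1 to POU2F3 (6852 to 13747), MYC to MYCL (14.2 to 23.9), TDP1 to TDP2 (0.696 to 0.345), MCL1 to BCL2 (17.2 to 46.3) and BCL2 to BCL2L1 (0.174 to 0.049). It also did for ABCC1 to ABCG2 (339 to 226), SLC31A1 to SLC31A2 (316 to 155), EZH2 to EZH1 (3.55 to 5.49), PARP1 to PARP2 (15.4 to 8.78) and DLL3 to SEZ6 (0.83 to 1.62), the 1 pair of these whose order turned.

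Among detected genes past the homogeneity test with a mean of at least 50 counts, the SD of log2 CPM over the libraries was largest for DNAH5, CDH11, ADM2, RAPGEF3, CAMK2A, COL21A1, RP11-42O15.3, ASS1, PPARA and CATSPERG. ASS1, the urea-cycle enzyme argininosuccinate synthase, stood at 21.3, 104 and 26.6 CPM in replicates 1, 2 and 3, and the peptide hormone gene ADM2 at 1.49, 11.6 and 4.92 CPM. The dynein gene DNAH5 stood at 0.926, 8.94 and 4.13 CPM, whereas the cadherin gene CDH11 was at 4.87, 1.36 and 0.584 CPM. Replicate 2 was the highest library for 9 of these 10 genes. A chi-square test of homogeneity with Benjamini-Hochberg adjustment called 10044 of 14612 detected genes (68.7%) spread beyond counting error, and 5708 without replicate 2. The common biological coefficient of variation was 15.5%, and the median SD of log2 CPM over the 3 libraries was 0.17.

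Between libraries, 462 detected genes differed by more than 2-fold between replicates 1 and 2, 286 between replicates 1 and 3 and 498 between replicates 2 and 3. The median chi-square per gene was 5.64, 3.21 and 6.05 for these pairs, against 0.455 for counting noise alone, so no pair agreed within sampling noise and each library was counted as 1 sample. Mitochondrial genes held 7.55%, 7.45% and 7.05% of the counts. Transcripts of low GC content were lower in replicate 2: in the fifth of genes with the lowest GC content the median log2 difference of replicate 2 from replicate 3 was -0.22, and in the fifth with the highest it was 0.12. The same medians were -0.15 and 0.046 for replicate 2 from replicate 1, and 0.076 and -0.075 for replicate 3 from replicate 1.

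**Figure D3:**
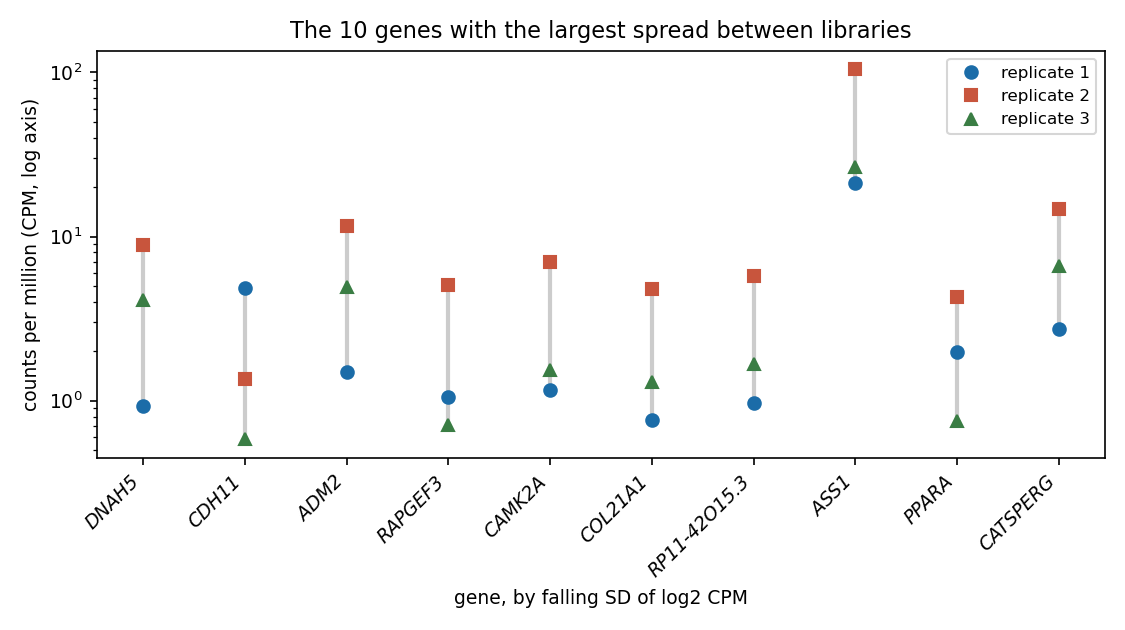
CPM (log axis) in each library for the 10 genes with the largest SD of log2 CPM among detected genes past the homogeneity test with a mean of at least 50 counts; each symbol is 1 library and the grey line joins the lowest and highest. Replicate 2 is the highest library for 9 of the 10 genes, and CDH11, highest in replicate 1, is the exception.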

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

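No test in this part was chosen after the result was seen. The 13 names that had been turned into dates held 64377 counts over the 3 libraries, 16633, 30165 and 17579 in replicates 1, 2 and 3, against a limit of 3 counts that a count of 0 allows. They drew attention because the comparisons of gene levels leave them out and yet they hold reads. Names of this kind arise from the SEPT, MARCH and DEC gene families in spreadsheets, and no gene of these was assigned here. No explanation was tested.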

How the results depend on the processing

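The alternative that left out genes with shared coding bases was chosen after the data were seen; the others were fixed before. Counts of genes above and below the median gene stayed within 1.5 times under each leave-one-out, the 1 CPM filter, DESeq2 size factors, plain totals, the prior count of 0.5 and limma-voom, and DESeq2 size factors, totals and the prior count changed no call of a list. Normalization cancels from a ratio within a library, so its alternatives say nothing about the pairs, and no paired analysis was possible because there is 1 group.

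Keeping genes with at least 1 count in any library gave 22026 genes, 10592 above and 10587 below the median gene, since more genes were tested. The random lists were then drawn from these 22026 genes, low counts included, and 9 lists were called high and 2 low. The 4 gained as high were the neuroendocrine, recombination, checkpoint and hypoxia lists. With the upper quartile as reference 3146 genes lay above and 10426 below, which follows from the higher reference. Lists called low numbered 3 with random lists matched on length, 2 on CPM per kb and 3 with protein-coding genes only, and from 1 without replicate 1 to 2 without replicate 2 or 3. The lists gained were the epithelial, NOTCH or interferon list, and with any count the fibroblast list and a list with too few detected members otherwise; the cause was not tested. Tuft-cell, fibroblast and endothelial markers had too few genes for a value with the 1 CPM filter. The count of genes spread beyond counting error ranged from 5708 without replicate 2 to 7888 without replicate 1, with 2 libraries in place of 3.

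Lists whose log2 distance from random lists turned sign were all without a call in either setting: the subtype factors (-0.050 to 0.17 over the leave-one-outs, 2.26 with any count, 0.010 matched on length, 0.035 per kb), p53 and its targets (-0.14 with the 1 CPM filter, -0.093 protein-coding only), apoptosis regulators (1.94 with any count), stemness genes (-2.90 with any count, -0.052 without genes with shared coding bases) and surface antigens (-0.47 per kb). The DLL3 to SEZ6 log2 ratio turned to 0.70 per kb, which follows from their lengths. For the lists the cause was not tested.

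Of the 6 calls, 3 were lost under an alternative: the endothelial list with any count (adjusted p = 0.279), and per kb the redox (0.0523) and chromatin lists (0.107). Depth limits genes such as POU2F3 and CDKN1A, whose ratios have wide intervals.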

Other observations

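The tests of depth and of GC content and length for the amino acid response genes were chosen after the result was seen. So was the difference of replicate 3 from replicate 1 for BMP target genes. The detection test of the lists and the differences of the fixed lists between libraries were also chosen then. The others were written down before the values they measure were seen. The use of an SD for stress of the endoplasmic reticulum was not written down.

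Interferon response genes were detected less often than other protein-coding genes: 6 of 19 (31.6%) against 69.8% (Fisher's exact test, adjusted p = 0.00469 over 35 lists). The same held for myeloid and lymphoid markers (1 of 9 each, adjusted p = 0.00402), erythroid (0 of 5, 0.0127), fibroblast (3 of 11, 0.0176) and lung epithelial markers (2 of 8, 0.0412). Proliferation genes (24 of 24, 0.00402), homologous recombination and Fanconi genes (23 of 23, 0.00402), nucleotide excision repair genes (17 of 17, 0.0127) and chromatin regulators (17 of 17, 0.0127) were detected more often. The other 25 lists did not pass this test.

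Genes listed here as the amino acid response, a name that states no trigger, differed between the libraries. ASNS, asparagine synthetase, stood at 216, 882 and 326 CPM in replicates 1, 2 and 3, CTH, cystathionine gamma-lyase, at 52.1, 201 and 86.3 CPM, PHGDH, the first enzyme of serine synthesis, at 144, 360 and 184 CPM, and the cystine transporter gene SLC7A11 at 53.5, 161 and 232 CPM. GDF15 had 8, 285 and 22 counts and FGF21 7, 244 and 32. These genes were chosen after their values were seen. Of the fixed lists, over 93 tests of list and library pair, the immediate early and stress genes were higher in replicate 2 than in replicate 1 by a median log2 of 0.35 and than in replicate 3 by 0.34, and NOTCH genes were lower in replicate 3 than in replicate 1, at -0.33 (permutation test, adjusted p = 0.0496 for each). The stress list shares ATF3, ATF4 and DDIT3 with the amino acid response genes, so its result is not separate from theirs. Not every member rose: HSPH1, among its 3 highest members, stood at 229, 137 and 233 CPM in replicates 1, 2 and 3. The random lists were matched on level and not on GC content, along which the libraries also differed. The stress and NOTCH differences were therefore not separated from GC content.

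A hypothesis is that the cultures behind the libraries differed in the strength of this response: over 17 response genes whose values had not been seen, the median log2 difference of replicate 2 from replicate 1 was 0.56, with 16 higher, against a central 95% of -0.15 to 0.12 in random lists matched on level. The 17 are further genes of the same response, so they cannot tell what set it off. Depth is argued against by replicates 1 and 3, of similar depth, which differed by a median log2 of 0.37 over all 55 response genes, 38 of them seen before, and by 0.13 over the 17 not seen (-0.09 to 0.09 in random lists). GC content and length are argued against by what was left after their trend was removed from the difference of replicate 2 from replicate 1, a median of 0.83 over all 55 (0.86 before) and of 0.49 over the 17 (0.56 before; -0.14 to 0.11 in random lists). Stress of the endoplasmic reticulum stays open, since its chaperones went both ways: their median was 0.057 (-0.15 to 0.11 in random lists), with 9 of 17 higher and an SD of 0.34, and DNAJB9, XBP1, SEL1L and HSPA5, named after their values were seen, stood in replicate 2 at 1.76, 1.71, 1.35 and 1.29 times their level in replicate 1. Among the chaperones that were lower, SDF2L1 and CALR, also named after their values were seen, stood at 0.755 and 0.836 times. The design names no difference between the libraries, so a difference in culture or handling stays open and may underlie the pattern.

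Replicate 2 was lower than replicate 3 for transcripts of low GC content, with a Spearman correlation across genes of 0.384 over 13518 genes, which are not independent replicates. The correlation was 0.240 for replicate 2 from replicate 1 and -0.205 for replicate 3 from replicate 1, so replicates 1 and 3 also differed along GC content. Transcript length alone is argued against by the correlation of replicate 2 from replicate 3 within 3 classes of genes by length, of which the lowest was 0.280 (0.107 for replicate 2 from replicate 1), and zinc finger genes alone by the 0.372 left without them. No biological explanation was tested, and a difference in library preparation may remain as an open explanation.

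Some genes that share most of their coding bases with another gene on the same strand had low counts. RPL17, a ribosomal protein gene, had 78, 183 and 77 counts and the glycolytic gene ALDOA 18, 42 and 27. A hypothesis is that reads on exons of more than 1 gene were left out of the counts. It was tested on the parts of read-through genes, which join a pair of neighbouring genes in 1 transcript. Of these parts, 90 had at least 90% of their coding bases shared with any other gene on the same strand, leaving out those already seen. Their median log2 CPM was -1.24, against a central 95% of 1.62 to 4.58 in random lists of protein-coding genes that share under 1%. Weak transcription of loci with read-through genes in general is argued against by 38 other parts with under 50% shared, whose median was 3.60 (0.47 to 4.98 in random lists). These 38 need not lie at the same loci as the 90, so weak transcription of the loci of the 90 stays open. Of 14 list genes that share at least 50% of their coding bases, ERCC5, NHEJ1, TAP2 and IRF9 had low counts, which may come from the counting, but BMI1, with all coding bases shared, had 961, 1587 and 1134 counts and BCL2L2 3856, 8945 and 4354, so a shared exon does not set the count of every such gene.

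ID1 (13.1, 6.01 and 4.46 CPM in replicates 1, 2 and 3), ID3 (21.1, 11.1 and 9.18 CPM), SMAD6 and NOG, chosen after their values were seen, were highest in replicate 1, and over 7 further BMP target genes the median log2 difference of replicate 1 from replicate 2 was 0.24 (-0.37 to 0.32 in random lists) and that of replicate 3 from replicate 1 was -0.51 (-0.34 to 0.26), which leaves a difference in BMP signalling undecided.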
